A study of Scyliorhinus canicula with 6 samples.

How the data were processed

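RNA-seq was performed on ventricle tissue of juvenile small-spotted catsharks (Scyliorhinus canicula), an egg-laying shark whose embryos develop in egg cases on the sea bed. Per the labels, embryos were incubated at 15 °C or at 20 °C, and hatchlings were then moved to a common environment at 15 °C for about 5 months before the ventricle was taken. Total RNA was extracted with a Qiagen kit and libraries were made with a stranded poly(A) kit, per the labels' protocols. There were 3 libraries per temperature, 6 in all. The group and the replicate number came from the sample titles. Each title refers to a juvenile, but no label states that the replicates of a group were separate animals or came from separate clutches, so p-values measure only the spread between these libraries.

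The authors' processing named Trimmomatic and kallisto, per the submitters' processing notes, without versions or options. The authors deposited 1 kallisto table per library, with the estimated count, TPM (transcript abundance scaled for length and depth), length and effective length of each of 347710 contigs, per the file headers. The estimated counts deposited by the authors are not whole numbers and are not normalised. In 2 libraries, 15 °C replicate 2 and 20 °C replicate 3, the count of 1 contig was deposited in exponent form with 3 digits, so that count and the library total are exact only to within 5000 counts. The deposited TPM values are the counts divided by effective length and scaled to a fixed sum in each library. The contigs carry names in the style of the Trinity de novo assembler. The assembly itself, its version and any annotation of it are not given in the sources used here. The 347710 contigs have a median length of 363 bases, and 238394 of the 269971 contig groups (below) hold 1 contig. An assembly of this kind holds fragments and sequence variants of one gene under several names, and the estimated counts divide reads between them, so a contig value is not always the level of a whole gene.

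The contig names encode 4 nested levels: the contig, the contig group that the assembler treats as a gene, the component and the read cluster. Counts were summed per contig group and rounded to whole numbers. The tables do not pair contigs with gene names, and 0 contig identifiers were found among the 29227 genes of the RefSeq table for assembly sScyCan1.1. The 20 functional gene lists and 12 cell type marker lists that had been fixed before the data were examined could therefore not be matched, and no test of them was run. These lists covered, among others, chaperones, contraction, calcium handling, metabolism, extracellular matrix and chromatin, and markers of blood, endothelium, fibroblasts and other cells that a ventricle sample can hold. No genome position is given for any contig.

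Contig groups were kept by the filterByExpr function of edgeR, which asks for about 10 counts in at least 3 libraries after scaling for depth and a total of at least 15. This left 31870 contig groups, holding 93.5% to 95.2% of each library's counts. The comparison of 20 °C with 15 °C used TMM normalisation and the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with temperature as the sole term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The same test was applied to 33317 single contigs. The share of each contig within its group was tested with the diffSpliceDGE function of edgeR on 3182 groups with at least 2 tested contigs, combining contig p-values per group by the Simes method. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. Distances between libraries were root-mean-square differences of log2 CPM (counts scaled for depth, prior count 2), and differences of single values between groups were tested by exact permutation, two-sided, which cannot go below 0.1 with 3 libraries against 3.

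The rule for contigs to be described was fixed before the data were examined. Without gene names it took the 2 contig groups higher and the 2 lower at 20 °C with the smallest p among those whose 3 libraries of one temperature did not overlap the 3 of the other. Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter at a mean of 10 counts, an offset for effective length, non-robust estimation, limma 3.58.1 on log2(TPM + 0.5) and log2(TPM + 0.05), a replicate term, and leaving out each library. A surrogate variable from sva 3.50.0, sums over components and read clusters, and thinning to the smallest library were added after the data were seen. The fold change of contigs near 0 on the log2(TPM + pseudocount) scale depends on the pseudocount.

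Replicate numbers occur in both groups, but the labels tie them to no animal, clutch or day. The deviations of same-numbered libraries from their group means correlated at 0.08, 0.18 and -0.02 for numbers 1, 2 and 3, and the numbers were not treated as pairs.

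The procedures were tested on simulated data with the means and library sizes of the real contig groups and 200 changed features. At a dispersion of 0.04 for all features, the edgeR test on 31870 contig groups recovered 22 of 50 changes of 2-fold, 49 of 50 of 4-fold and 50 of 50 of 8-fold, with 7 unchanged groups called. The contig test recovered 14, 48 and 50 of 50 at the same folds, and the test of contig shares recovered 198 of 200 groups in which 1 contig was raised 8-fold. With the dispersions estimated from these 6 libraries, the edgeR tests on contig groups and on contigs each recovered 0 of 50 changes at each of 2-, 4-, 8- and 16-fold. The test of contig shares was not simulated at these dispersions. DESeq2 on data simulated with the real dispersions called 40 of 46 changes of 16-fold and also 100 unchanged groups among 27289 tested.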

Results

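The question addressed was whether the temperature of embryonic development leaves a difference in gene expression in the heart of the juvenile that persists after months at a common temperature. Ventricle RNA was compared between 3 libraries of juveniles incubated at 20 °C and 3 of juveniles incubated at 15 °C. The total estimated count was 2977166, 12954558 and 2397973 for the 15 °C replicates 1, 2 and 3, and 5310811, 4137455 and 5070116 for the 20 °C replicates. The 15 °C replicate 2 thus had 5.4 times the reads of the shallowest library, and detection of rare contigs differed accordingly, from 103083 contigs with a count above 0 in 15 °C replicate 3 to 186425 in 15 °C replicate 2.

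The ventricle transcriptome was dominated by few contig groups at both temperatures. The 20 most abundant contig groups held 27.2% ± 2.48 of the TPM at 15 °C (SD, n = 3) and 28.1% ± 5.82 at 20 °C (SD, n = 3), and the groups did not differ beyond the spread (exact permutation p = 0.9). By mean CPM, which is not scaled for length, the most abundant contig group was TRINITY_DN137200_c0_g1, with a longest contig of 3726 bases. It was at 151587 ± 60288 CPM at 15 °C and 179498 ± 89608 CPM at 20 °C. Its counts in 15 °C replicate 2 and 20 °C replicate 3 were deposited in exponent form with 3 digits. Its log2 fold change was 0.24, with a 95% confidence interval from -0.95 to 1.44. TRINITY_DN137200_c2_g1, from the same read cluster, was at 70058 ± 39014 CPM at 15 °C and 46464 ± 12872 CPM at 20 °C. TRINITY_DN119020_c0_g1 was at 46127 ± 15732 and 48156 ± 16613 CPM. These abundant contig groups were chosen for description after their values were seen. Of the 20 contig groups with the highest mean CPM, 8 had a higher and 12 a lower fitted mean at 20 °C. None passed the edgeR test, with adjustment over all groups or adjusted over the list alone (0 in both), and the smallest unadjusted p among them was 0.0869.

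The number of contig groups at 1 TPM or more was 70918 ± 3877 at 15 °C and 74916 ± 6384 at 20 °C (SD, n = 3 each, exact permutation p = 0.4). After thinning to the smallest library the numbers were 71316 ± 908 and 71447 ± 5762, and the difference shrank from 3998 to 131 contig groups.

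Libraries of one temperature were on average no closer to each other than to libraries of the other temperature. Pearson correlations of log2 CPM across the 31870 tested contig groups ranged from 0.53 to 0.66 for the 6 pairs within a temperature, with a mean of 0.61. For the 9 pairs between temperatures they ranged from 0.57 to 0.71, with a mean of 0.62. Contig groups are not independent replicates, so these values describe the libraries. The mean root-mean-square distance was 1.63 log2 units within and 1.62 between temperatures, a difference of -0.02, and 6 of the 10 ways to split the libraries into 3 and 3 gave a difference at least as large (exact permutation p = 0.6, smallest possible 0.1). Without 15 °C replicate 1 the difference was 0.09, and without 15 °C replicate 2 it was 0.06 (exact permutation p = 0.2 in both). The first principal component carried 31.5% of the variance and did not separate the temperatures. On it, 15 °C replicate 1 stood with 20 °C replicates 1 and 3, and 15 °C replicates 2 and 3 stood with 20 °C replicate 2.

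**Figure D1:**
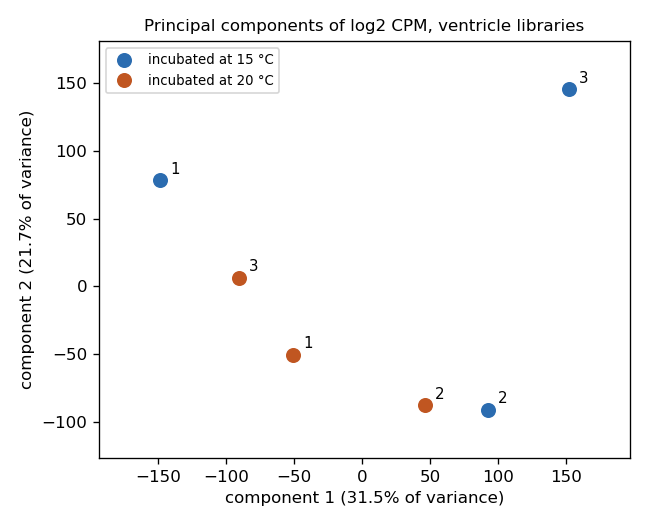
Principal components 1 and 2 of log2 CPM over the tested contig groups, with the share of variance on each axis. Points are the 6 ventricle libraries, coloured by embryonic temperature and numbered by replicate; both temperatures have libraries on each side of component 1, which carries 31.5% of the variance.

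No contig group passed the test for a difference between temperatures. In edgeR's quasi-likelihood test, 0 of 31870 contig groups had an adjusted p under 0.05, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 618 contig groups, 1.94% of those tested, of which 306 were higher and 312 lower at 20 °C. With 1 library left out, when the filter keeps more contig groups, still 0 passed. Without 15 °C replicate 1 the number at an unadjusted p under 0.05 was 1830 of 38224 (4.79%, smallest adjusted p 0.459). It was 947 of 34417 (2.75%) without 15 °C replicate 2 and 1006 of 37963 (2.65%) without 20 °C replicate 2. Leaving out each other library gave 646 to 780. All these shares lay under the 5% that a test gives on average without any difference. In the other 9 splits of the 6 libraries into 3 and 3 the share was 1.36% to 7.19%, and at most 2.94% in all but the highest. A share under 5% is thus no evidence here that a difference is absent. Splits with 1 library left out were not run. By other tools, DESeq2 called 51 contig groups, 25 higher and 26 lower at 20 °C, and limma called 1 on either TPM scale. DESeq2 called 38 to 586 contig groups in the other 9 splits of the same libraries into 3 and 3. The 3 libraries of one temperature lay wholly above or below the other 3 in 2913 contig groups, 9.14% of those tested, where chance gives 10%. Of these, 1584 were higher and 1329 lower at 20 °C.

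Libraries of one temperature differed widely. The common biological coefficient of variation was 0.69, and the median 95% confidence interval of a fold change reached 1.55 log2 units to either side. For 48.2% of the tested contig groups the unadjusted interval excluded a 4-fold change in either direction, and in the third with the highest level this share was 72.9%. In data simulated with this spread and 200 changed among 31868 contig groups, the test recovered 0 of the 50 changed 16-fold. A small number of changes of that size among all contig groups would thus mostly be missed. The limit is not absolute, as the same test called 3 contig groups in another split of these libraries into 3 and 3.

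Of the 4 contig groups chosen by rule, 2 had no counts in any 15 °C library, 1 had 1 count over the 20 °C libraries, and 1 was detected in all 6 libraries. TRINITY_DN166199_c0_g1, a single contig of 428 bases, had 0 counts in each 15 °C library and 134, 186 and 116 counts in the 20 °C libraries, or 31.8 ± 7.55 CPM (SD, n = 3). Against the 3 counts over the group that a count of 0 allows (0.170 CPM), it was at least 187-fold higher at 20 °C. That limit rests mainly on the deep 15 °C replicate 2, and without this library it was at least 52.6-fold (0.605 CPM). TRINITY_DN36587_c0_g2, a single contig of 1116 bases, likewise had 0 counts at 15 °C and 19.1 ± 2.62 CPM at 20 °C, at least 112-fold higher, or at least 31.5-fold without 15 °C replicate 2. These limits cover counting error only. TRINITY_DN140607_c1_g5, a group of 11 contigs of up to 458 bases, was at 32.7 ± 4.21 CPM at 15 °C and 7.71 ± 0.397 CPM at 20 °C. Its log2 fold change was -2.08 with a standard error of 0.286. With the offset for effective length it was -1.59, and limma gave -1.59 on log2(TPM + 0.5) and -1.60 on log2(TPM + 0.05). The other alternatives gave -2.14 to -1.98. TRINITY_DN138344_c1_g2, a group of 2 contigs of up to 3276 bases, had 121 counts over the 15 °C libraries and 1 count over the 20 °C libraries. The ratio of 15 °C to 20 °C was 94.1, with an exact binomial interval from 16.6 to 3745 that covers counting error only. Without 15 °C replicate 2 the ratio was 169 (interval from 29.2 to 6771), and without 20 °C replicate 1, which held the 1 count, the group was at least 28.0-fold higher at 15 °C. The unadjusted p-values in edgeR's test were 4.90e-05, 8.80e-05, 2.17e-04 and 4.85e-04 in this order, and the adjusted p was 1.00 for each, so none passed. DESeq2 called all 4, but they were chosen by p and lack of overlap in the same counts, so this is no separate support. Gaps this wide were also not particular to temperature. Contig groups with a gap of at least 16-fold (on CPM + 0.5) between the nearest libraries of opposite sides numbered 4 for temperature. The other 9 splits of the libraries into 3 and 3 gave 6 to 47.

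**Figure D2:**
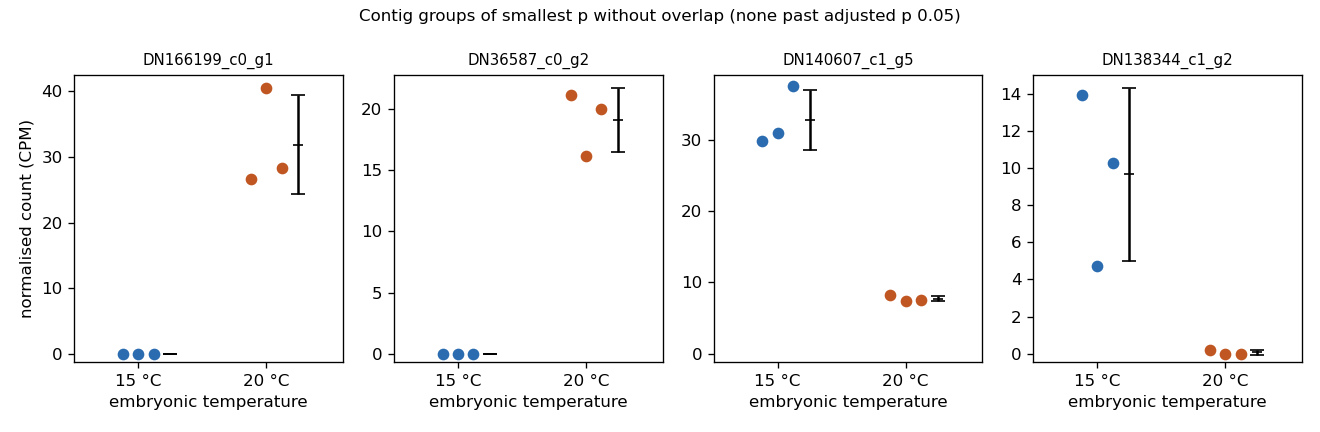
Normalised counts (CPM) of the 4 contig groups chosen by rule, by embryonic temperature. Points are single libraries (n = 3 per temperature), and bars give the mean and SD; TRINITY_DN166199_c0_g1 and TRINITY_DN36587_c0_g2 are at 0 in all 15 °C libraries, and none of the 4 passed adjustment in the edgeR test.

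For single contigs, which separate alternative transcripts and sequence variants, 0 of 33317 passed the edgeR test. The smallest adjusted p was 1.00, and 536 contigs, 1.61%, had an unadjusted p under 0.05, with 268 in each direction. With 1 library left out, 0 passed and 835 to 1704 contigs, 2.15% to 3.93% of those then tested, had an unadjusted p under 0.05, most without 15 °C replicate 1 (smallest adjusted p 0.120), and 1261 (3.33%) without 15 °C replicate 2. DESeq2 called 205 contigs, 103 higher and 102 lower at 20 °C, and limma on log2(TPM + 0.5) called 2. The common coefficient of variation was 0.93 for contigs.

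The makeup of contig groups was compared to learn whether the mixture of contigs within a group differed between temperatures. In edgeR's diffSpliceDGE test, 0 of 3182 contig groups passed by the Simes method, with a smallest adjusted p of 0.413 and 84 groups, 2.64%, at an unadjusted p under 0.05. With 1 library left out, 0 passed and 149 to 245 groups had an unadjusted p under 0.05, most without 15 °C replicate 1 (245 of 5061, 4.84%), with a smallest adjusted p of 0.0976 without 20 °C replicate 3. By the F test of the same fit, the number that passed was also 0, with 124 groups at an unadjusted p under 0.05. What the test of contig shares recovers at the spread of the real contigs was not simulated, so the lack of calls does not exclude changed shares.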

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

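All alternatives except the surrogate variable, the sums over components and read clusters and the thinned counts were chosen before the data were examined. The alternatives planned for the gene lists were not run, as no list could be matched to contigs. For contig groups the count of 0 was also found with RLE size factors, the stricter filter, the length offset, non-robust estimation, 1 surrogate variable, sums per component or read cluster, and thinned counts. Leaving out each library in turn gave 0 calls in every case for contig groups, contigs and contig shares. The count moved to 51 with DESeq2, 137 without the low-count filter (82 higher and 55 lower at 20 °C), 1 with limma on log2(TPM + 0.5) and 1 with limma on log2(TPM + 0.05). For contigs it moved to 205 with DESeq2, 210 without the filter and 2 with limma on log2(TPM + 0.5). Of the 51 groups called by DESeq2, 31 were at 0 in all libraries of one temperature. Of the 137 called without the filter, 86 were at 0 in all libraries of one temperature. The temperatures did not overlap in 57 of the 137, against all 51 called by DESeq2. Of the same 137, 80 were not among the groups tested with the filter, 12 had counts in 1 library alone, and 34 were shared with DESeq2. The cause was not tested. With the replicate number as a block, 0 contig groups, 0 contigs and 0 contig shares passed, and 472, 332 and 51 had an unadjusted p under 0.05. Of the 3 numbers, 1 had its same-numbered library as the best match in both directions.

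The difference of 0.952 percentage points in the share of the 20 most abundant contig groups turned to -0.920 when shares of counts replaced TPM, and ranged from -1.98 (without 20 °C replicate 3) to 3.84 when a library was left out, with -0.336 without 15 °C replicate 2. The difference of 3998 contig groups at 1 TPM turned to -181 at 0.1 TPM and ranged from 630.5 to 6980 with a library left out. The distance difference of -0.02 ranged from -0.109 to 0.0923, above 0 without 15 °C replicate 1 or without 15 °C replicate 2 (0.0610). None of these values passed an exact test, and these designs could not reach 0.05; the cause was not tested. TRINITY_DN166199_c0_g1 passed in 4 of 17 alternatives (adjusted p from 8.87e-19, in edgeR without the low-count filter, to 1). TRINITY_DN36587_c0_g2 passed in 2 of 17, TRINITY_DN140607_c1_g5 in 1 of 17 and TRINITY_DN138344_c1_g2 in 2 of 16. Each kept its direction in all of them. The rule took only groups without overlap between the temperatures, so a kept direction was nearly fixed in advance and is no support. The 10624 contig groups with the lowest level had a median mean count of 14.3 and a median interval of 2.21 log2 units to either side. In the 10623 with the highest level these were 93.3 and 1.08. The median biological coefficient of variation was 0.70 and 0.46 in this order, so the spread beyond counting error differed too. How much of the interval width was due to depth was not separated.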

Other observations

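The tests on surrogate variables, on deeply counted groups, on opposed contig pairs, and on splits at the level of contigs and contig shares were specified before their results were seen. The other tests, and the simulations of what each test recovers, were chosen after. Among abundant contig groups, some were nearly present or absent by library without following temperature. TRINITY_DN129078_c0_g2, of 1765 bases, was at 12601 and 13829 CPM in 15 °C replicates 2 and 3 and at 8153 CPM in 20 °C replicate 2, and at 86.0, 36.6 and 297 CPM in 15 °C replicate 1 and 20 °C replicates 1 and 3. TRINITY_DN123335_c0_g1, of 2248 bases, showed the opposite, with 8096, 6639 and 8925 CPM in those last 3 libraries and 3.15, 1.34 and 9.80 CPM in the first 3. Their sum ranged from 6676 to 13830 CPM, with a coefficient of variation of 28.7% against 112% and 111% for each alone. The pair was picked because of these values.

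The temperature split was set beside the other splits of the same 6 libraries into 3 and 3. There are 10 splits, too few for a share under 0.05. The edgeR test called 0 contig groups in the real split and at most 3 in another, 0 contigs against at most 2, and 0 contig shares against at most 10, and since no split can give fewer than 0, that all 10 splits gave as many says nothing. DESeq2 called 51 contig groups in the real split, and 9 of the 10 splits, the real one included, gave 51 or more, with 586 in the highest other. Contig groups at 0 in all 3 libraries of one side and at 5 CPM or more in each of the other numbered 7 for temperature and 8 to 63 for the other splits. Each of these highest values belonged to the split of 15 °C replicate 1 and 20 °C replicates 1 and 3 from the rest. In that split DESeq2 called several times the real count. The first principal component of the same libraries makes the same split. The high counts thus describe a structure of the samples that crosses the temperatures but are not separate support for it.

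For the lack of calls between temperatures, 3 technical explanations were weighed. Among the 821 contig groups with a mean of 500 counts or more, 0 passed with adjustment over these groups alone and 2.44% had an unadjusted p under 0.05, in a test that recovered 4 of 50 simulated 2-fold, 37 of 50 4-fold and 47 of 50 16-fold changes. That simulation changed 200 of the 821 groups, which eases the adjustment, and recovery with few changed groups was not simulated. The lack of calls argues against changes of 4-fold or more in many of these groups. Their median biological coefficient of variation was 0.40, while counting alone gave a median of 0.032. Counting error was thus a small part of their spread, which argues against low depth as the reason in these 821 groups. The test does not speak to few changed groups, to changes of 2-fold or to the groups with fewer counts. With 1 surrogate variable, which followed the first principal component (r = 0.99 over the 6 libraries), 0 contig groups passed and the share with an unadjusted p under 0.05 was 3.09%, up from 1.94%; summed over read clusters, 0 of 26677 passed and the share was 2.44%. Both shares stayed under the limit of 5% set for them and within those of the other 9 splits, 1.75% to 6.96% and 1.78% to 7.46%, so they show no sign of a change in a large part of the contig groups. As the other splits lie on both sides of that limit and the adjusted tests recovered 0 of 50 and 13 of 50 simulated 16-fold changes, the crossing structure and the splitting of genes over contig groups stay open, as do a true absence of a lasting effect and one too small for 3 libraries with this spread.

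For the first principal component, the mean fragment length implied by the effective lengths followed the component over the 6 libraries (Pearson r = 0.81, exact permutation p = 0.0278, adjusted over 3 relations 0.0833; Spearman rho = 0.89, exact permutation p = 0.0333, adjusted 0.1). Without 15 °C replicate 3 and 20 °C replicate 3, the 2 libraries farthest from the median, r was 0.69. Log2 total count gave r = 0.12 (exact permutation p = 0.826, adjusted 0.826; rho = -0.03, p = 1) and 0.39 without its 2 farthest libraries, and the share of the 20 most abundant groups gave r = -0.62 (exact permutation p = 0.2, adjusted 0.3; rho = -0.71, p = 0.136) and -0.72. With 6 libraries, neither fragment length nor library size can be told apart from other differences between the libraries. No biological explanation was tested, as the labels give no sex, clutch or size.

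The spread between libraries of one temperature was large, with a coefficient of variation of 0.69 for contig groups. Pairs of contigs of one contig group were strongly opposed across libraries (correlation of their deviations from group means under -0.8) in 12.1% of 3182 groups, against 4.49% of random pairs, a ratio of 2.70. For components of one read cluster the shares were 15.96% and 5.44%, but for contig groups of one component they were 8.10% and 5.15%, with a median r of 0.07. Strongly parallel pairs (over 0.8) made up 6.98% against 6.38% of random pairs within contig groups, 12.2% against 6.16% within components and 4.59% against 6.41% within read clusters. The contig and read cluster levels are consistent with reads of one gene moving between contigs from library to library, while contig groups of one component were parallel more often than opposed. Movement between contigs of one contig group is already summed out of the 0.69. The common coefficient of variation was 0.93 for contigs, 0.69 for contig groups, 0.64 for components and 0.56 for read clusters. Such movement is thus a candidate explanation for part of the spread of contigs. For contig groups it can account for a part at most, as the spread was still 0.56 after summing over read clusters. Sequence variants that differ between the sampled juveniles, alternative transcripts, and the division of ambiguous reads by the estimation would each give this, and none was separated here.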
